A study of Mus musculus with 24 samples.

How the data were processed

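The 24 libraries hold RNA from bone marrow cells of C57BL6/J mice, sorted as HSPCs, B cells or T cells. The extraction protocol in the labels names 30000 sorted HSPCs for all 24, including those labelled B and T cells. The deposited values are counts, raw fragment counts per gene from featureCounts v2.0.1 on paired reads with reverse strandedness and the GENCODE M28 annotation, per the file headers. The submitters' processing notes name FastQC, STAR and Subread without versions and both mm10 and mm39. The coordinates in the files are those of GRCm39. Read trimming and alignment settings are not given in the sources used here. Of the mutant allele the file headers give only the word het, for untreated, doxorubicin and 20-week HSPCs, or Mut, for the 2-week libraries.

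The files list 55414 genes, and 52081 IDs took a symbol from the GENCODE M21 table, which left 3333 without one, while 99.85% of the counts fell in genes with a symbol. A further 68 IDs shared a symbol with a gene of more reads and are named by ID. The headers place the files in 3 directories, one with untreated and doxorubicin HSPCs, one with all 2-week libraries and one with 20-week HSPCs, which were taken as batches. Replicate numbers in the headers differ from those in the labels for some libraries. The deviations of replicates from their group mean correlated at -0.13 to 0.14 between the genotypes of one cell type and condition, and at 0.19 between WT B and WT T libraries and 0.03 between mutant ones. WT B and mutant T libraries, which differ in genotype, also reached 0.19. Between HSPC groups of different conditions the values ran from -0.25 to 0.20. Erythroid genes took a larger share of the counts in replicate 1 than in replicate 2 of all 4 B and T groups, from 2.36% against 1.38% in WT B cells to 0.837% against 0.416% in mutant T libraries, so a factor shared by B and T libraries stays open. The labels name no pairs, and libraries were not paired.

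HSPC libraries and B and T libraries were fitted separately. Genes were filtered with filterByExpr at its minimum of 10 counts and total of 15, which kept 19522 and 17484 genes. Libraries were scaled by TMM and fitted in edgeR 4.0.16 by robust quasi-likelihood with 1 mean per group. The 17 contrasts compare mutant with WT in each condition and cell type, their mean over the 4 HSPC conditions, each condition with untreated HSPCs in each genotype, and the differences of these effects. Calls have a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Of the 32 gene lists fixed before the data were examined, those with at least 5 tested genes were tested by camera of limma 3.58.1 on voom values with a preset correlation of 0.01, again with an estimated correlation, and by fry. Of 227 list calls with the preset correlation 1 held with the estimated one, the p53 targets after doxorubicin in mutants.

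Named genes were chosen by a rule written before the data were examined: Srcap, the 10 largest changes in each direction among called genes with an average log2 CPM of at least 1, with both libraries of one group above both of the other, and up to 4 members of each list. For the mean over the 4 HSPC conditions, the condition on libraries was instead the same sign of the mean difference in each. For differences of effects there was none. Unnamed gene models and members named beyond this rule, such as Gm42047, Gm43305, Bmpr1a and the cell type markers given per library, were chosen after their values were seen. Values of some genes that the rule picks are not reported here. Folds against groups with no count use a floor of 3 counts per library and cover counting error only.

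The methods were tested on simulated data with 200 changed genes at 2-fold or 4-fold. In untreated HSPCs edgeR called 32.3% of the 2-fold and 58.3% of the 4-fold changes among 18417 genes, with 7 false calls against 26 in DESeq2, and 64.6% and 81.2% in the mean over conditions, with 13 false calls. In B cells it called 38 and 55 of them, 40.4% and 56.7%, among 16425 genes with 23 false calls, and in libraries labelled T cells 45.7% and 56.7% with 15 false calls. In these comparisons the share of false calls among all edgeR calls lay above the threshold of 0.05, most so in B cells. Of 200 lists of unchanged genes, 2 to 6 passed camera at an unadjusted p under 0.05 and 8 to 17 passed fry. The simulated genes varied independently of each other, so these rates do not cover lists whose genes vary together.

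The alternatives were DESeq2 1.42.0, RLE size factors, no count filter, the replicate number as a block, fits of the compared groups alone and each library left out in turn. Added after seeing the data were fits without immunoglobulin genes and Jchain, without genes of chromosomes X and Y, with genotype and replicate number as a block shared by B and T libraries, the list tests without WT untreated replicate 1, and correlations under other settings. Leave-outs that leave 1 library in a group assume that it varies like the other groups. Analyses ran in R 4.3.3 and Python 3.11.15 with statmod 1.5.0, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.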

Results

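The series measured poly(A) RNA by stranded sequencing in 24 mouse libraries sorted from bone marrow, of which 16 are labelled hematopoietic stem and progenitor cells (HSPCs), 4 B cells and 4 T cells. The HSPCs were WT or Srcap mutant and untreated, exposed to doxorubicin for 12 hours, taken 2 weeks after transplantation, or taken 20 weeks after competitive transplantation, with 2 libraries in each of the 8 groups. The B and T cell libraries, 2 of each genotype, come from 2 weeks after transplantation. Srcap encodes the ATPase of a complex that places the histone variant H2A.Z in chromatin, and per the series title the study concerns clonal hematopoiesis and DNA repair. Total counts per library, in units of 1e6, ran from 26.4 to 78.4. Group means below are CPM, read counts scaled by library size, ± SD with n = 2 libraries, and log2 fold changes carry their SE. With 2 libraries per group, p-values measure spread only between these samples, which the labels call independent without saying that they are separate animals.

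Srcap itself (ENSMUSG00000053877, GRCm39 chromosome 7, 127111155 to 127160391) was detected in every library. In untreated HSPCs it stood at 8.71 and 8.47 CPM in the WT libraries and 13.7 and 11.8 CPM in the mutant ones, before library scaling. After doxorubicin the WT libraries held 8.93 and 10.7 CPM and the mutant ones 10.8 and 11.9 CPM. At 2 weeks the values were 14.4 and 13.7 CPM in WT and 11.7 and 13 CPM in mutant HSPCs, and at 20 weeks 6.11 and 7.18 CPM in WT and 2.83 and 7.92 CPM in mutant HSPCs. B cell libraries held 20.3 and 13.8 CPM in WT and 16.2 and 20 CPM in mutants, and libraries labelled T cells 6.09 and 7.46 CPM in WT and 6.52 and 5.7 CPM in mutants. No genotype comparison called Srcap in edgeR, with fitted log2 changes between -0.33 at 20 weeks and 0.54 in untreated HSPCs. The 20-week estimate was 0.26 without mutant replicate 1 and -1.33 without mutant replicate 2. Without mutant 20-week replicate 2 the mean over the HSPC conditions was -0.20, and the B and T estimates near 0 also changed sign in 2 leave-outs each.

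The libraries differed in the cell type genes they carried. Kit and Cd34, markers of stem and progenitor cells, were at 311 to 601 CPM and 417 to 1100 CPM in the HSPC libraries, against at most 5.93 and 3.5 CPM in the B cell libraries. Cd79a, a part of the B cell receptor, was at 1030 to 1350 CPM in the B cell libraries. In the libraries labelled T cells, Cd3e, a chain of the T cell receptor complex, reached only 0.0883 to 1.56 CPM, while the neutrophil granule genes S100a8 and Ltf stood at 20600 to 26200 CPM and 16200 to 18900 CPM. The neutrophil and granulocyte list took 14.9% to 16.9% of the counts there, against 0.398% to 1.39% in B cell libraries. WT untreated replicate 1 held 2.54% of its counts in that list, where the lowest library of its condition held 0.0546%. Immunoglobulin genes and Jchain took 16.9% to 26.7% of the counts in HSPCs at 20 weeks and 3.66% to 6.22% in untreated HSPCs. Xist, expressed from the inactive X chromosome, was at 545 CPM or more in the 2-week HSPC libraries and at most 0.484 CPM in the other HSPC libraries, which carried the Y-linked gene Ddx3y instead. The B cell libraries and those labelled T cells, also from 2 weeks, held Xist at 320 CPM or more, so all 2-week libraries were female and the others male. Genotype comparisons stay within one sex and one header directory.

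**Figure D1:**
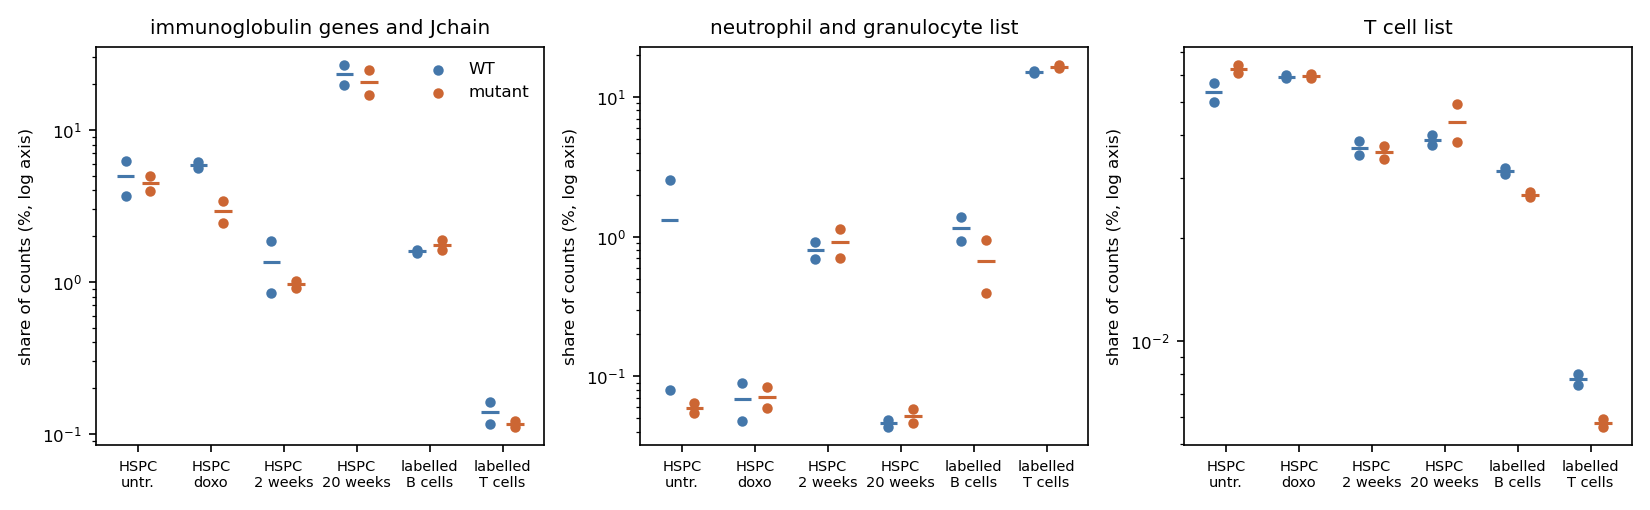
Share of counts, in percent on a log axis, taken by immunoglobulin genes and Jchain, by the neutrophil and granulocyte list and by the T cell list in each of the 24 libraries, with WT in blue, mutant in orange and bars at the means of n = 2. The 4 libraries labelled T cells lie at 14.9% to 16.9% for the granulocyte list and at 0.00562% to 0.00802% for the T cell list.

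The first comparison asked how Srcap mutation changed untreated HSPCs, and no gene passed the test. Members of the neutrophil and granulocyte list were lower in mutants, 22 of 22, with a median log2 change of -4.98, and this followed WT replicate 1, which carried the granulocyte RNA described above. Cell division genes of the G2 and M phase list were higher in mutants in 30 of 30 cases, with a median of 0.27, and homologous recombination genes, which repair DNA breaks, in 29 of 35, with a median of 0.17. Camera gave adjusted p = 6.35e-07 for the G2 and M phase list and 0.00193 for homologous recombination, but adjusted p = 0.463 and 0.389 with an estimated correlation. The granulocyte list had adjusted p = 9e-11 and adjusted p = 0.389 with an estimated correlation, and 12 of its members fell when adjusted over the list alone against 0 over all genes. Without WT replicate 1 its median was -0.36. Of 19522 genes, edgeR called 0, 941 had an unadjusted p under 0.05, and DESeq2 called 134. Leaving out WT replicate 2, which left the library with granulocyte RNA as the only WT sample, gave 235 genes.

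After doxorubicin, a DNA-damaging drug, 3 genes differed between mutant and WT HSPCs. Ankle1, which encodes an endonuclease, rose from 7.54 ± 0.633 CPM in WT to 30.8 ± 8.52 CPM in mutants, 4.09-fold, with a log2 change of 2.03 ± 0.31 and adjusted p = 0.0267. Akr1c13, an aldo-keto reductase gene, fell from 41 ± 0.806 to 17.1 ± 1.23 CPM, with a log2 change of -1.26 ± 0.20 and adjusted p = 0.0401. The third call was the gene model Gm42047, at 1.69 with adjusted p = 0.00882. G2 and M phase genes were higher in 30 of 30 cases with a median of 0.29, and 2 of them passed when adjusted over the list alone against 0 over all genes: Cenpa, a centromere histone, at 132 ± 11.9 CPM in mutants and 66 ± 7.29 CPM in WT, and Nuf2, a kinetochore gene. Homologous recombination genes were higher in 28 of 35 cases, with Rad51ap1 at 0.74 ± 0.17 and Rad54b at 0.79 ± 0.20 among the 4 that rose and 1 that fell when adjusted over the list alone, against 0 over all genes. The Fanconi anaemia gene Fanca, at 0.75, and the p53 targets Pidd1, at 0.83, and Psrc1, at 0.82, likewise passed over their lists alone. Stem cell genes were lower, with a median of -0.33, and Hlf and Cd34 fell when adjusted over the list alone. Camera's adjusted p was 5.48e-08 for G2 and M phase, 0.000973 for homologous recombination and 1.25e-05 for stem cell genes. These became adjusted p = 0.473, 0.377 and 0.423 with an estimated correlation. In edgeR 1912 genes had an unadjusted p under 0.05, DESeq2 called 210 and a fit of the compared groups alone 256. Leaving out WT replicate 1 or mutant replicate 2 left 0 calls, WT replicate 2 left 1 and mutant replicate 1 left 2. Ankle1 and Gm42047 stayed called only without mutant replicate 1 and Akr1c13 in none, with log2 ranges of 1.72 to 2.29, 1.53 to 1.83 and -1.34 to -1.19.

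Transplantation makes donor cells rebuild the blood system, and 2 weeks later 27 genes differed between mutant and WT HSPCs, 24 of them lower in mutants. Klhl4 fell 6.77-fold, from 2.94 ± 0.166 to 0.42 ± 0.126 CPM, with a log2 change of -2.76 ± 0.38 and adjusted p = 0.00558. Npdc1 fell from 0.824 ± 0.0616 CPM in WT, with a log2 change of -4.79, which was -8.34 without mutant replicate 2 and -3.48 without mutant replicate 1. Ndn, a gene linked to stem cell quiescence, stood at 0.89 ± 0.22 CPM in WT and had no count in either mutant library. Against a floor of 3 counts per library Ndn was at least 10.4-fold lower. Tmem136 was at least 9.28-fold lower and Spint1, at 0.701 ± 0.24 CPM in WT, at least 8.19-fold lower. Eda2r, an X-linked p53 target, was at least 8.13-fold lower. These bounds cover counting error only. Fewer genes had any count in the mutant libraries, 17795 and 18326, than in WT, 21603 and 19903. Of these libraries mutant replicate 1 had the most total counts, 49779482. Lower detection of weakly expressed genes in the mutant libraries is thus not covered by the bounds. It could contribute to the 24 lower genes and was not tested. Among the genes that rose, Igf2bp3, an RNA-binding protein gene of fetal stem cells, went from 1.83 ± 0.285 to 7.59 ± 0.543 CPM, and the light chain segment Iglv2 from 0.141 ± 0.0844 to 45.7 ± 10.1 CPM. The third was the gene model Gm43305, at 2.07 ± 0.31. Megakaryocyte and platelet genes were lower in 19 of 21 cases with a median of -0.41, and the platelet integrin Itga2b, at -0.88 ± 0.21, fell when adjusted over the list alone. B cell genes were higher in 19 of 27 cases with a median of 0.45, but their share of the counts was not, at 0.736% and 0.85% in mutants and 0.723% and 1.19% in WT, with Ighm at 3540 ± 1500 and 6060 ± 2500 CPM. The mutant libraries also differed from each other, with 740 genes over 2-fold apart after 1 CPM was added, against 201 for WT, and Mpo at 2210 and 5260 CPM. Camera's adjusted p was 1.3e-06 for the megakaryocyte list and 6.96e-07 for the B cell list, and adjusted p = 0.164 and 0.51 with an estimated correlation. Unadjusted p was under 0.05 for 1711 genes, DESeq2 called 241, a fit of the compared groups alone 2 and the replicate block 11. The count was 12 without WT replicate 1, 11 without WT replicate 2, 14 without mutant replicate 1 and 681 without mutant replicate 2. Klhl4, Npdc1 and Iglv2 stayed called in all 4, while Ndn, Tmem136, Spint1, Eda2r, Igf2bp3 and Gm43305 were each lost in 1 or more, with Igf2bp3 at 1.90 to 2.22. The log2 change of Iglv2 was 8.27, and 9.09 without WT replicate 2.

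At 20 weeks after competitive transplantation, which asks how mutant donor cells compare after long-term engraftment, 1 gene differed. Hsph1, a heat shock chaperone gene, rose from 88.9 ± 4.94 CPM in WT to 202 ± 13.3 CPM in mutant HSPCs, 2.27-fold, with a log2 change of 1.18 ± 0.16 and adjusted p = 0.0158. Other heat shock genes of the immediate early and handling stress list were also higher, with Dnajb1 at 0.48 ± 0.15, Hspa8 at 0.45 ± 0.14 and Hspa1b at 2.90 ± 0.95, and these 3 and Hsph1 passed when adjusted over the list alone. That list had camera adjusted p = 0.0265 and adjusted p = 0.69 with an estimated correlation. Ribosomal protein genes were higher in 47 of 49 cases with a median of 0.23, though they took 7.7% of the counts in mutant replicate 1 and 4.83% in mutant replicate 2, against 5.44% and 4.96% in WT. G2 and M phase genes were lower in 28 of 30 cases with a median of -0.24. The adjusted p of these lists was 2.37e-07 and 6.36e-05, and adjusted p = 0.69 for both with an estimated correlation. Unadjusted p was under 0.05 for 742 genes, and DESeq2 called 18 and edgeR without a count filter 149. The counts were 1, with another gene, without WT replicate 1, 0 without WT replicate 2, 1 without mutant replicate 1 and 289 without mutant replicate 2. Hsph1 was lost without either WT library, at 1.11 to 1.25 over the leave-outs.

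Averaged over the 4 HSPC conditions, 26 genes differed between the genotypes, 7 higher and 19 lower in mutants. Klhl4 was lower in both mutant libraries of all 4 conditions, with a log2 change of -1.77 ± 0.17 and adjusted p = 5.92e-05, and went from 18.2 ± 6.7 to 4.8 ± 1.2 CPM in untreated HSPCs. Akr1c13 fell by 0.80 on the log2 scale, with adjusted p = 0.00215, and Rps4l, which resembles a ribosomal protein gene, had a log2 change of -1.57 ± 0.22 with adjusted p = 0.00746. Npdc1, at -1.57, the axonemal assembly gene Dnaaf3, at -1.08, C1qtnf6, from 9.69 ± 2 to 4.52 ± 1.7 CPM in untreated HSPCs, and Msl3l2, at -0.65, also fell. Ndn fell in the mean as well, from 9.17 ± 2.7 to 4.65 ± 0.32 CPM in untreated HSPCs. So did the nucleotidyltransferase-like gene Mb21d2, from 5.64 ± 0.2 to 3.71 ± 1.3 CPM there. Neither had a count in the mutant 2-week libraries, in which fewer genes had any count than in WT. Their mean folds are thus no bound and are not given. Ndn was lower in both mutant libraries in only 2 of the 4 conditions. Of the genes that rose, Tfrc, the receptor for iron uptake, went from 148 ± 0.83 to 226 ± 36 CPM in untreated HSPCs and had a mean log2 change of 0.52 ± 0.09 with adjusted p = 0.0174. The natural killer cell receptor gene Klrb1c, at 0.91, and Tbc1d10c, at 0.48, rose too. Megakaryocyte and platelet genes were lower in 21 of 21 cases with a median of -0.34, and 7 fell when adjusted over the list alone against 0 over all genes, among them Itga2b at -0.41. Stem cell genes were lower in 22 of 30 cases with a median of -0.16. Camera's adjusted p was 2.19e-06 and 0.00013, and adjusted p = 0.191 and 0.548 with an estimated correlation. Klhl4 and Akr1c13 stayed called in all 16 leave-outs, at -1.88 to -1.67 and -0.86 to -0.73, while Rps4l and Npdc1 were lost only without mutant untreated replicate 2, Npdc1 was at -2.45 without mutant 2-week replicate 2 and -1.24 without mutant 2-week replicate 1, and every other gene named here as rising or falling over all genes was lost in 8 or more. The count was 24 without mutant untreated replicate 1 and otherwise moved: 12 and 110 without WT untreated replicates 1 and 2, 2 without mutant untreated replicate 2, 10 and 15 without the WT and 10 and 128 without the mutant 20-week replicates, 7 and 10 without the WT and 40 and 306 without the mutant 2-week replicates, 14 and 12 without the WT and 14 and 5 without the mutant doxorubicin replicates. With the replicate number as a block 5 genes were called.

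**Figure D2:**
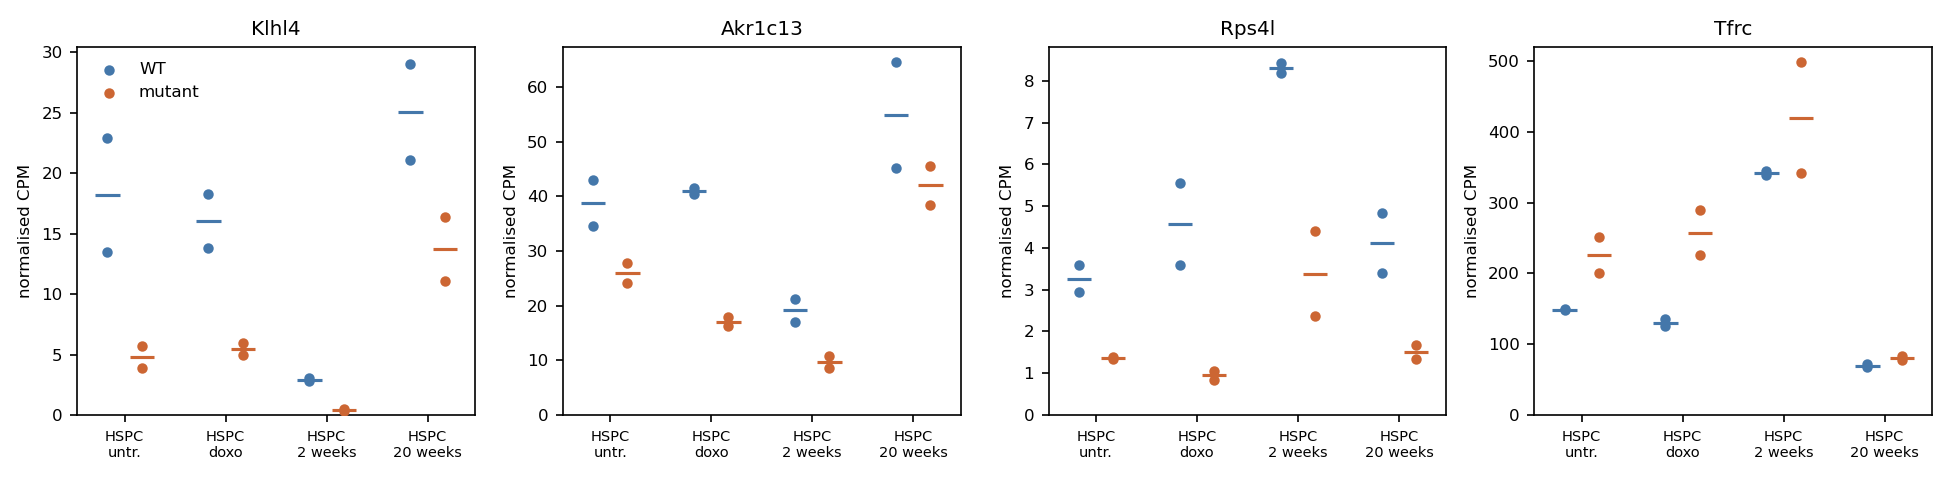
Normalised CPM of Klhl4, Akr1c13, Rps4l and Tfrc in the 16 HSPC libraries by condition, with WT in blue, mutant in orange and bars at the means of n = 2. Klhl4 and Rps4l lie lower in both mutant than in both WT libraries in each of the 4 conditions.

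The response to doxorubicin was compared with untreated HSPCs within each genotype. In WT HSPCs 1 gene changed: Mid1, a ubiquitin ligase gene, fell 14.5-fold, from 4.85 ± 0.725 to 0.33 ± 0.134 CPM, with adjusted p = 0.0214. In mutant HSPCs edgeR called 0 genes, 411 had an unadjusted p under 0.05, and DESeq2 called 8. The p53 target list, the textbook transcriptional response to DNA damage, was higher in 31 of 36 cases in mutants, with a median of 0.33, camera adjusted p = 3.77e-12 and adjusted p = 0.0126 with an estimated correlation. Zmat3 stood at 15 ± 3.15 against 6.69 ± 1.11 CPM, and Zmat3, Psrc1, Aen and Ccng1 rose when adjusted over the list alone, each with adjusted p = 0.017, against 0 over all genes. In the same mutant libraries immunoglobulin genes and Jchain took 3.38% and 2.43% of the counts after doxorubicin and 4.95% and 3.99% untreated. The WT shares, 6.18% and 5.6% against 3.66% and 6.22%, overlapped. In WT the p53 list was higher in 26 of 36 cases with a median of 0.17 and camera adjusted p = 0.0215, and adjusted p = 0.391 with an estimated correlation. Over the list alone Slc19a2, at 0.88, and the cell cycle inhibitor Cdkn1a, at 0.84, rose there and Gadd45a, at -1.44, fell, though it was at -0.54 without WT untreated replicate 1, which carried granulocyte RNA, and -1.99 without WT untreated replicate 2. MYC target and ribosome biogenesis genes were higher in 24 of 26 cases in WT and 26 of 26 in mutants, with adjusted p = 0.151 and 0.0998 with an estimated correlation. Interferon response genes had a median of -0.44 in WT and -0.25 in mutants, with adjusted p = 0.391 and 0.29 with an estimated correlation, and the WT median was -0.29 without WT untreated replicate 1. The test of the difference between the genotypes' responses called 0 genes in edgeR, with 550 at an unadjusted p under 0.05 and 5 in DESeq2, and the p53 list differed by a median of 0.13, with camera adjusted p = 0.0257 and adjusted p = 0.539 with an estimated correlation. Leaving out WT untreated replicate 2 gave 217 genes in WT and 85 for the difference, and WT doxorubicin replicate 2 gave 1 for the difference. In WT the count was 0 without untreated replicate 1 or doxorubicin replicate 1, and 1, another gene, without doxorubicin replicate 2. Mid1 stayed called only without untreated replicate 2, at -4.35 to -3.50. In mutants 2 genes were called without doxorubicin replicate 1.

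**Figure D3:**
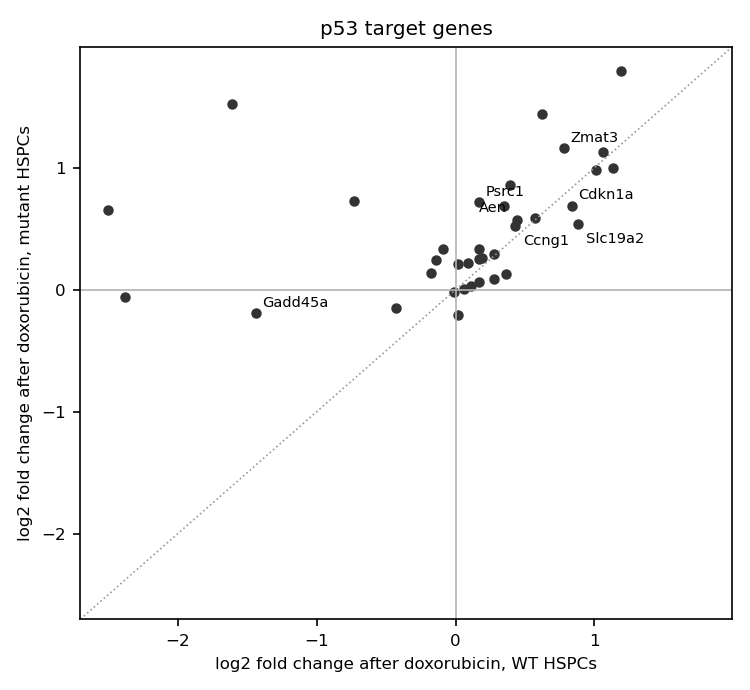
Log2 fold change after doxorubicin of the p53 target genes in WT (x axis) and mutant (y axis) HSPCs, each point 1 gene and the dotted line at equality. The median was 0.17 in WT and 0.33 in mutant HSPCs.

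At 2 weeks after transplantation HSPCs differed from untreated ones in many genes, but the 2-week libraries are female and come from another header directory, so stress, batch and sex cannot be told apart. Erythroid genes rose in both genotypes, 20 of 26 in WT and 26 of 26 in mutants. The libraries differed in myeloid and mitochondrial RNA too: Mpo, a gene of granulocyte precursors, was at 2210 to 5260 CPM at 2 weeks and 123 to 168 CPM in untreated libraries. The neutrophil and granulocyte list took 0.696% to 1.14% of the counts at 2 weeks, against 2.54% in WT untreated replicate 1 and 0.0546% to 0.0795% in the other untreated libraries, and mitochondrially encoded genes took 1.12% to 1.31% against 2.9% to 3.57%. Epor, the erythropoietin receptor, went from 1.14 ± 0.433 to 56.1 ± 0.228 CPM in WT, 49-fold, with a log2 change of 5.62 ± 0.44 and 5.65 in mutants, there 6.25 without untreated replicate 2, and the erythroid transcription factor Gfi1b rose by 3.31 and 3.24. Ribosome biogenesis genes of the MYC list rose in 25 of 26 cases in each genotype, with Rrp12 at 2.02 and Mybbp1a at 1.55 in WT, and S phase genes in 26 of 35 cases in WT and 28 of 35 in mutants, with Ccne1 at 2.54 and Cdt1 at 1.55 in WT. Stem cell genes fell in 20 of 30 cases and rose in 3 in each genotype: Hlf went from 503 ± 76.4 to 57.5 ± 4.6 CPM in WT, and Procr changed by -2.98. Early lymphoid priming genes fell in 16 of 21 cases and rose in 1 in each genotype, with Flt3, a cytokine receptor, at 244 ± 18 against 761 ± 22.8 CPM in WT, and Lax1 at -1.93. Immunoglobulin genes and Jchain took 0.845% to 1.86% of the counts at 2 weeks against 3.66% to 6.22% untreated, and the plasma cell list 0.083% to 0.266% against 0.55% to 0.78%. Of the SRCAP complex and H2A.Z list 8 of 12 genes rose in WT and 7 of 12 in mutants, with the ATPase Ruvbl2 at 1.58 and 1.42 and Znhit1 at 1.25 and 1.27. With an estimated correlation the adjusted p was 0.103 for the erythroid list, 0.0505 for MYC, 0.103 for S phase, 0.178 for stem cells, 0.103 for lymphoid priming and 0.103 for the SRCAP list in WT, and 0.0788, 0.0572, 0.196, 0.268, 0.175 and 0.196 in mutants. In all 5820 genes were called in WT, 2929 up and 2891 down, and 6690 in mutants, 3065 up and 3625 down. The genotypes shared 2322 genes up and 2223 down, against 460 and 537 for independent lists, and the responses correlated across genes with Spearman rho = 0.60. Every gene named as rising or falling in this comparison kept its call in each leave-out. The difference between the responses called 0 genes in edgeR, with 1432 at an unadjusted p under 0.05 and 120 in DESeq2. The mutant count was 4278 without untreated replicate 1. For the difference it was 151 without WT untreated replicate 2, 160 without mutant 2-week replicate 2, 5 without mutant 2-week replicate 1, and 1 without WT untreated replicate 1 or WT 2-week replicate 1.

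At 20 weeks after competitive transplantation HSPCs again differed from untreated ones across header directories, with both sets male. Vwf, a gene of platelet-biased stem cells, rose 6.83-fold in WT, from 9.18 ± 1.66 to 62.8 ± 9.35 CPM, with a log2 change of 2.77 ± 0.24 and 2.72 in mutants. Selp, the platelet adhesion gene, rose by 3.96 and 3.78, the former 3.30 without WT 20-week replicate 1, and the stem cell marker Ly6a by 1.71 and 1.67. Plasma cell genes rose in 11 of 17 cases in WT and 13 of 17 in mutants, among them the secretory regulator Xbp1 by 1.42 and 1.36 and Mzb1 by 2.49 in WT. MHC class II genes rose in 6 of 10 and 9 of 10 cases, with Cd74 by 2.57 and 3.52 and H2-Ab1 by 2.40 in WT. Without WT untreated replicate 1 the WT counts were 6 of 17 and 2 of 10. These groups moved together with the immunoglobulin share, 16.9% to 26.7% at 20 weeks against 3.66% to 6.22% in untreated HSPCs. The lymphoid chromatin organiser Satb1 fell by 1.08 in WT and 1.52 in mutants. In mutants 15 of 30 G2 and M phase genes fell, with Bub1 at -0.93, and 10 of 35 homologous recombination genes fell and 1 rose, with Brca2 at -0.94, Rad54b at -1.06 and Blm at -0.95, while WT had 1 and 0. The genotypes' difference was a median of -0.48 for G2 and M phase, with camera adjusted p = 6.96e-11 and adjusted p = 0.411 with an estimated correlation. For homologous recombination it was -0.27, with 0.00279 and adjusted p = 0.411 with an estimated correlation, and no single gene was called in the test of the difference. With an estimated correlation the adjusted p was 0.099 and 0.159 for the plasma cell list, and 0.099 and 0.129 for MHC class II, in WT and mutants. The neutrophil receptor gene C5ar1 fell in WT, from 26.8 ± 34.8 CPM in untreated libraries of which replicate 1 carried granulocyte RNA, and stayed called only without WT untreated replicate 2. Altogether 861 genes were called in WT, 528 up, and 2825 in mutants, 1519 up, with 450 up and 247 down in both against 41.1 and 22.3 for independent lists. DESeq2 called 1906 in WT. The WT count was 130 and 542 without untreated replicates 1 and 2, and 491 and 174 without 20-week replicates 1 and 2. The mutant count was 1176 and 704 without untreated replicates 1 and 2 and 1188 without 20-week replicate 1. Brca2 was lost without mutant untreated replicate 2 or mutant 20-week replicate 1, at -1.29 to -0.66. The difference called 0 genes in edgeR, with 910 at an unadjusted p under 0.05 and 14 in DESeq2, and 131 without WT untreated replicate 2 and 40 without mutant 20-week replicate 2.

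In B cells sorted 2 weeks after transplantation, 112 genes differed between mutant and WT, 102 of them lower in mutants. Monocyte genes were among the lower ones: the chemokine receptor Ccr2 fell from 41.9 ± 0.293 to 23.4 ± 4.28 CPM, with a log2 change of -0.84 ± 0.15 and adjusted p = 0.0238, and Ly6c2 from 94 ± 16.2 to 45 ± 11.8 CPM. The phagocyte gene Cd68 changed by -0.57. The monocyte, macrophage and dendritic cell list was lower in 25 of 25 cases with a median of -0.77, 3 of them called and 9 when adjusted over the list alone. The neutrophil list was lower in 22 of 22 with a median of -0.76, and took 0.931% and 1.39% of the counts in WT against 0.941% and 0.398% in mutants, so mutant replicate 1 was no lower than WT replicate 1. The T cell list had a median of -0.61, while B cell genes were higher in 23 of 27 cases with a median of 0.22. Interferon-induced genes Oas3, at -0.85, Irf7, at -0.67, and Isg15, at -0.84, fell, and so did the linker histone gene H1f0, at -1.29 ± 0.16 with adjusted p = 0.00248. Crtac1 at -4.90, the lymphatic marker Lyve1 at -3.72 and the myeloid receptor Cd300e at -3.42 also fell, from under 1 CPM in WT. Crtac1 was at -3.96 without mutant replicate 1 and -7.77 without mutant replicate 2, and Lyve1 at -8.40 and -2.78. Eps8l1, an actin regulator gene, rose from 0.312 ± 0.0933 to 17.6 ± 1.17 CPM, and Fgd6 by 0.79 and the chromatin reader Brwd1 by 0.53. S phase genes were lower in 35 of 35 cases with a median of -0.29. Camera's adjusted p was 1.02e-13 for monocytes, 7.67e-13 for neutrophils, 3.96e-13 for S phase, 4.06e-05 for B cells and 0.0138 for interferon genes. These became adjusted p = 0.341, 0.341, 0.341, 0.41 and 0.773 with an estimated correlation, and for the T cell list adjusted p = 6.63e-05 became adjusted p = 0.278 with an estimated correlation. In the simulated data edgeR made 23 false calls in this comparison beside 38 and 55 right ones. Unadjusted p was under 0.05 for 1928 of 17484 genes, DESeq2 called 326, a fit of the compared groups alone 3 and the replicate block 242. The count was 112 without WT replicate 1, 43 without WT replicate 2, 458 without mutant replicate 1 and 15 without mutant replicate 2. H1f0 and Crtac1 stayed called in all 4 leave-outs, Irf7 in none and Cd300e and Ly6c2 in some. Ccr2, Cd68, Oas3, Isg15, Lyve1, Eps8l1, Fgd6 and Brwd1 stayed called only without mutant replicate 1, with Ccr2 at -1.04 to -0.67.

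**Figure D4:**
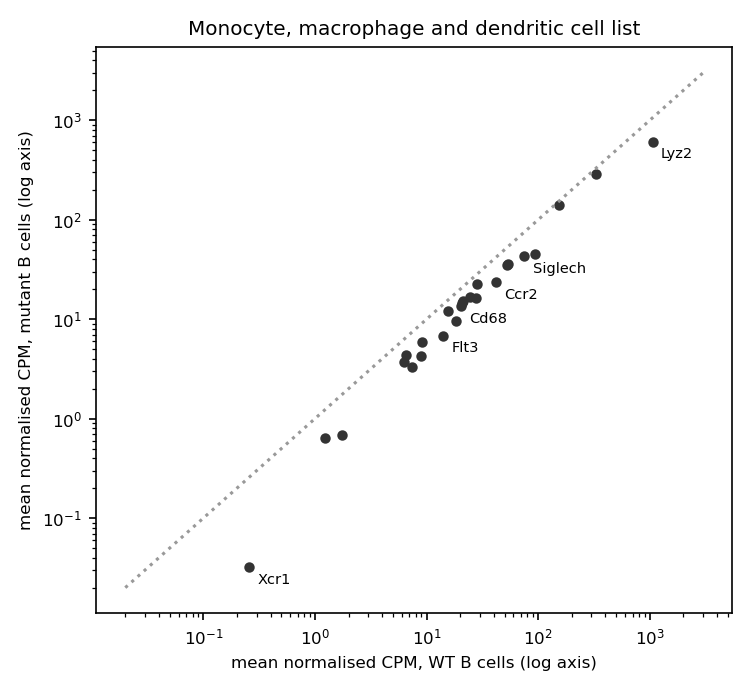
Mean normalised CPM of the 25 monocyte, macrophage and dendritic cell genes in WT (x axis) and mutant (y axis) B cell libraries, both on log axes, n = 2 libraries each, with the dotted line at equality. All 25 points lie below the line, with Lyz2 the highest at 1060 and 609 CPM.

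In the libraries labelled T cells, which carried neutrophil genes and almost no T cell genes, 2 genes differed. The gene model Gm43305 rose, with a log2 change of 2.42 ± 0.22 and adjusted p = 0.000846, and Trib2, a pseudokinase gene, fell from 12.7 ± 0.23 to 6.07 ± 0.813 CPM, with a log2 change of -1.07 ± 0.14 and adjusted p = 0.0364. Erythroid genes were lower in 26 of 26 cases with a median of -0.76 and camera adjusted p = 6.55e-25, and adjusted p = 0.406 with an estimated correlation. They took 1.31% and 0.79% of the counts in WT and 0.837% and 0.416% in mutants, so mutant replicate 1 was no lower than WT replicate 2. Unadjusted p was under 0.05 for 1000 genes, and DESeq2 called 23. The count was 5, 2, 3 and 1 without WT replicates 1 and 2 and mutant replicates 1 and 2, and 87 with the replicate block. Gm43305 kept its call in each and Trib2 in none, at -1.16 to -0.86.

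The genotype effect differed between B cells and libraries labelled T cells for 3 genes. Nlrp1a, an inflammasome sensor gene, was at 3.47 ± 0.35 CPM in WT and 0.58 ± 0.071 CPM in mutant B cells, and at 25.3 and 28.7 CPM in the libraries labelled T cells. Its difference was -2.76 ± 0.33, with adjusted p = 0.018. Plekhg1, at -2.14 ± 0.29, and the autophagy gene Dram1, at -1.49 ± 0.20, each had adjusted p = 0.0204, and all 3 stood higher in the libraries labelled T cells than in WT B cells. Unadjusted p was under 0.05 for 1286 genes and DESeq2 called 132. No gene was called without any 1 of the 4 libraries labelled T cells or without mutant B cell replicate 2. The count was 354 without mutant B cell replicate 1, and 19 and 9 without WT B cell replicates 1 and 2.

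The genotype effects in untreated and doxorubicin-exposed HSPCs correlated across genes at Spearman rho = 0.26, and at 0.55 over genes of at least 8 CPM. The other pairs of genotype effects ran from -0.22 to 0.17 over such genes. By Pearson r this pair stood out less, at 0.12, and at 0.19 over such genes, below 0.27 between untreated HSPCs and B cells. Untreated and doxorubicin-exposed HSPCs are also the only HSPC conditions that share a header directory. Gm43305 was called higher in mutants in 2-week HSPCs, in B cells and in the libraries labelled T cells, and Bmpr1a, a BMP receptor gene, lower in 2-week HSPCs and B cells. Genes are not independent replicates, so no p-value is given for these correlations.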

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

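The tests chosen only after the result was seen are those of Srcap-linked variants, of monocytes among the B cells, and all 3 on the libraries labelled T cells.

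For 3 genes the genotype effect differed between B cells and libraries labelled T cells by the test of that difference: Nlrp1a at -2.76, Plekhg1 at -2.14 and Dram1 at -1.49. In WT they stood at 3.47, 2.73 and 4.88 CPM in B cells and at 25.3, 52.7 and 91.6 CPM in the libraries labelled T cells. Cells of the latter kind among the sorted B cells could add to the WT B cell levels. The test thus cannot place the difference within B cells.

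The libraries labelled T cells carried granulocyte genes and almost no T cell genes. T cells with a few granulocytes would hold more T cell RNA than HSPCs, but the T cell list took at most 0.00802% of the counts against at least 0.0341% in HSPCs. The median ratio of 6 T cell receptor complex and signalling genes was 0.61, with Cd3d at 8.06 and Trac at 1.14 as exceptions and with Lck and Lat, the lowest, expressed in HSPCs at 55.4 and 34.6 CPM. An exchange with another library of the series would leave one with T cell levels of Cd3e, and the highest in any of the 24 was 1.95 CPM. Mostly granulocytes in the sorted fraction remains a candidate explanation, with the lowest of 5 mature neutrophil genes at 479 CPM, as does a swap with libraries outside the series, which was not tested.

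In B cells, 102 genes were lower in mutants, and 96 of them, 94.1% against 45.6% of all tested genes, stood higher in the libraries labelled T cells than in WT B cells. Fewer cells of that granulocyte-rich kind may contribute: by S100a8 and S100a9 their share was 3.77% and 6.57% in WT and 3.96% and 1.69% in mutants, and the whole WT share, an upper limit, would cover the fall for 51 genes, while the drop of the mean share would cover it for 5 and a median of 45.9% of each fall. The 283 other genes of at least 5 CPM in WT and over 10-fold higher in the libraries labelled T cells had a median of -0.57, against -1.19 for the 102, which were picked by their fall, so how much such cells explain stays open. Library size is argued against by a median expected count of 430. Of the monocyte, macrophage and dendritic cell list 21 of 25 genes were lower in both mutant libraries, where 16.7% is the chance for any given gene. Genes that come from the same cells move together, so a chance ordering of the libraries could place most of the list there. Lyz2 and Ly6c2 were among the 21 but not Irf8, at 328 and 291 CPM, or Ctss, at 154 and 139 CPM. But 20 of the 25 stood higher in the libraries labelled T cells than in WT B cells. For these the direction cannot tell fewer monocytes or macrophages from fewer granulocyte-rich cells, whose genes the sorted B cell libraries still carried. Siglech, from 75.1 to 43.3 CPM, and Bst2 and Flt3 were lower in both mutant libraries. They stood lower in the libraries labelled T cells than in WT B cells, Siglech at 5.39 CPM, so fewer granulocyte-rich cells cannot account for their falls. Irf8 and Xcr1, also lower there, were not lower in both mutant libraries. A change within B cells stays open and was not tested.

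For the 26 genes called over the HSPC conditions, 1 of 100 drawn splits within conditions, the real one, gave as many, and the highest other gave 3. This argues against an arbitrary division of the libraries. The other splits mix the genotypes, so a difference other than genotype that the libraries of a group share is not covered. Of the 26 genes, 0 lie within 20 Mb of Srcap, where 0.58 would be expected by chance. For these genes that argues only against local effects of variants carried along within that window. Effects of such variants on genes elsewhere are not covered, and variants elsewhere in the donors' background remain possible. Immunoglobulin RNA in the scaling is argued against as well, since 25 of the 26 kept their calls without those genes and the other, Iglv2, is one of them and was not tested. An effect of Srcap mutation thus stays a hypothesis, found and tested on the same libraries.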

How the results depend on the processing

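The fits without immunoglobulin genes and Jchain, without genes of chromosomes X and Y, with a block shared by B and T libraries, and the correlations under other settings were chosen after seeing the data. In the order untreated, doxorubicin, 2 weeks, 20 weeks and the mean over conditions, DESeq2 called 134, 210, 241, 18 and 302 genes between the genotypes of HSPCs, and edgeR without a count filter 467, 474, 399, 149 and 618. For the doxorubicin response they called 170 and 500 genes in WT and 8 and 177 in mutants, and for the 20-week response in WT 1906 and 1929. For the differences of the doxorubicin, 2-week and 20-week responses DESeq2 called 5, 120 and 14 genes and the unfiltered fit 337, 468 and 375. In B cells, libraries labelled T cells and their difference DESeq2 called 326, 23 and 132 and the unfiltered fit 590, 145 and 357. Fits of the compared groups alone called 256 after doxorubicin, 2 at 2 weeks and 4 at 20 weeks, 7 and 14 for the doxorubicin response in WT and mutants, 1 and 1 for the differences of the doxorubicin and 2-week responses, 3 in B cells and 0 in libraries labelled T cells. With the replicate block, which the labels do not show to be pairs, the counts were 11 at 2 weeks, 0 at 20 weeks, 5 for the mean, 3 for the difference at 2 weeks, 242 in B cells, 87 in libraries labelled T cells and 27 for their difference. The block shared by B and T libraries gave 265, 85 and 35. Without immunoglobulin genes and Jchain 7 genes were called after doxorubicin and 1 for its response in mutants, and RLE size factors gave 1 in the libraries labelled T cells. Of 227 list calls, 1 held with an estimated correlation, and fry called 81. Over the leave-outs the genotype counts in HSPCs ran from 0 to 235 untreated, 0 to 2 after doxorubicin, 11 to 681 at 2 weeks, 0 to 289 at 20 weeks and 2 to 306 for the mean. The doxorubicin response ran from 0 to 217 in WT and 0 to 2 in mutants, the 2-week response from 3973 to 4447 and 4278 to 6164, and the 20-week response from 130 to 542 and 704 to 3096. The differences of responses ran from 0 to 85, 0 to 160 and 0 to 131, B cells from 15 to 458, libraries labelled T cells from 1 to 5 and their difference from 0 to 354. Srcap, not called anywhere, changed sign at 20 weeks (-1.33 to 0.26), in the mean (-0.20 to 0.20), in B cells (-0.17 and -0.09 against a highest of 0.39) and in libraries labelled T cells (0.14 and 0.08 against a lowest of -0.17). The cause was not tested, except that the unfiltered and single-comparison fits test other genes or fewer samples. Counts with RLE size factors otherwise stayed within 1.5 times of the reported ones, and of the named genes 126 of the values kept their side of the threshold and 3 lost it. In the simulated data 32.3% of the 2-fold changes were called in untreated HSPCs, 30 of the 42 above 32 CPM, and 64.6% in the mean over conditions.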

Other observations

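All values here were picked after the data were seen.

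Eps8l1 and the gene model Gm43305 had higher means in mutants than in WT in every kind of library from 2 weeks after transplantation. Eps8l1 was at 0.0858 ± 0.12 CPM in WT and 7.07 ± 0.99 CPM in mutant HSPCs, at 0.397 ± 0.12 and 22.5 ± 1.7 CPM in B cells, and at 0.171 ± 0.24 and 8.36 ± 2.3 CPM in the libraries labelled T cells, before library scaling and with n = 2 each. It was called in B cells, while adjusted p was 0.289 in 2-week HSPCs and 0.226 in the libraries labelled T cells. In untreated HSPCs the order was the opposite, at 17.6 ± 6.1 CPM in WT and 5.62 ± 2.6 CPM in mutants. Gm43305, on chromosome 14, stood at 15.1 ± 3.9 CPM in WT and 89.6 ± 2.4 CPM in mutant B cells, and at 25.9 ± 3.4 and 29.7 ± 8 CPM in untreated HSPCs. At 20 weeks Gm43305 stood at 6.74 ± 0.91 CPM in WT and 13.4 ± 4.1 CPM in mutants, and Eps8l1 at 11.6 ± 0.6 and 14.8 ± 1.2 CPM. Each was higher in both mutant libraries there, but neither was called. After doxorubicin Eps8l1 ran from 0.648 to 20.9 CPM over the 4 libraries. Gm43305 was higher in both mutant libraries in only 2 of the 4 HSPC conditions. Gm43305 was also called in the mean over the 4 HSPC conditions, at 0.91 with adjusted p = 0.0169.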
